A study of Mus musculus with 12 samples.

How the data were processed

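RNA of mouse cells was profiled on 12 Affymetrix whole-transcript gene arrays, 1 array for each combination of genotype and stage. Of these, 6 arrays came from Mbd3+/+ (WT) cells, 4 from Mbd3flox/- (flox/-) cells and 2 from Mbd3-/- (-/-) cells. Embryonic fibroblasts (MEF) gave 3 arrays, MEF treated with doxycycline (DOX) to switch on the reprogramming factors Oct4, Sox2, Klf4 and Myc (OSKM) gave 5 arrays, and pluripotent lines gave 4 arrays: 2 of induced pluripotent stem cells (iPSC) and 2 of embryonic stem cells (ESC). DOX-treated WT cells were sampled at days 4, 8 and 11, and DOX-treated flox/- cells at days 4 and 8. Per the labels, the cells were grown in ESC medium with LIF and inhibitors on irradiated feeder fibroblasts, so feeder RNA can be in every sample. The label of the -/- MEF names no OSKM transgene. The WT day 8 and WT ESC arrays were reused from an earlier series, and the sources of the WT day 8 array name both 4 and 8 days; it was taken as day 8, as its title says.

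The authors extracted RNA with TRIzol, labelled it with biotin and scanned the arrays. The values deposited by the authors are in log2 units, from 3.11 to 13.99, for 35512 probe sets. The summary and normalization methods behind them were not given in the sources used here. The deposited values of all 12 arrays were used, and 0 columns were left out. A choice made before the data were examined was to apply quantile normalization if the medians of the arrays differed by more than 0.1. They differed by 0.122, so the values were quantile normalized.

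Of the probe sets, 23410 were in the annotation of the arrays, 21789 of them with a single symbol, 1621 with several symbols and 12102 not listed. Probe sets with several or no symbols were left out. Entrez identifiers linked 21698 probe sets to the RefSeq gene table of GRCm38.p6, and 0 symbols had to be replaced. The probe sets stood for 19938 genes. For the 999 genes with several probe sets, the probe set with the highest mean was taken. Genes above the median of the array on at least 1 array were kept, which left 13044 genes. Array intensities have no sequencing depth, and with 1 array per group the number of arrays limits the precision.

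Differential expression was tested with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8), by moderated statistics with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. The comparisons were the 4 pluripotent arrays against the 3 MEF arrays, the 5 DOX-treated arrays against the 3 MEF arrays, and the 5 DOX-treated arrays against the 4 pluripotent arrays. In these, arrays of the same cell state and of different genotype or day stood as replicates, so the spread within a state includes genotype and day. The flox/- genotype was compared with WT over the 8 arrays of the 4 stages that both have, with stage as a block, so that arrays were matched by stage, while no label says which arrays share a culture. The -/- genotype was compared with WT over the 7 arrays without DOX, with stage and genotype as terms. Stated errors are standard errors (SE) of the limma fit, and standard deviations (SD) are over the arrays of a group. Where the lower signal of a gene lies near or below the lower quartile of its array, the background limits the fold and its rank.

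Within a single stage each genotype has 1 array, so no test between arrays was possible there. Genes at least 2-fold apart were counted, and the median difference of each gene list was placed among 10000 random lists matched on mean expression. This percentile compares genes with genes and carries no measure of the variation between cultures.

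For the position of each DOX-treated array between MEF and iPSC, the difference of the array from the MEF of its own genotype was projected onto the difference between iPSC and MEF of that genotype, with 0 at MEF and 1 at iPSC. The 95% intervals come from 1000 bootstrap resamples of genes and carry no variation between cultures. The mean positions of flox/- and WT arrays were compared with an exact two-sided permutation test over all 10 splits of the arrays.

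The 22 gene lists were written before the data were examined, with 472 entries, of which 435 were measured and 377 kept. They cover pluripotency, the reprogramming factors, fibroblast and mesenchymal, epithelial, NuRD complex, cell cycle, senescence and p53, trophoblast, primitive endoderm, primed epiblast and early lineage, germline and methylation-sensitive, 2-cell-like, TGF-beta response, interferon response, chromatin modifier, X- and Y-linked sex, imprinted, macrophage and other blood-cell, endothelial, muscle, neural and keratinocyte genes. Lists were tested with camera of limma, a competitive test against all other genes, with the preset correlation between genes and again with an estimated correlation, each adjusted over the 22 lists. Genes of each list were counted as called over all genes and after adjusting over the list alone. Some genes are on a pair of lists, among them Pou5f1, Sox2 and Klf4 (pluripotency and reprogramming factors), Tet1 and Dnmt3l (pluripotency and chromatin modifiers), Dnmt3a and Dnmt3b (primed epiblast and chromatin modifiers), Acta2 (fibroblast and TGF-beta), Perp (keratinocyte and senescence), Peg10 (trophoblast and imprinted) and Zim1 (2-cell-like and imprinted).

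Genes were named by a fixed rule. Mbd3 came first, in every array. Each limma comparison then gave up to 10 called genes per direction with the largest log2 change, and list members in the order of the size of their log2 change. Each pair of single arrays gave 5 genes per direction with the largest difference, and list members in the same way. Hprt, Xist and the fibroblast and macrophage genes named across arrays outside this rule were chosen after their values were seen.

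The pipeline was tested on simulated data with 200 changed genes among 13044. At a true log2 change of 1 it recovered 74% of them in the comparison of pluripotent cells with MEF, 36% in DOX-treated cells against MEF, 41% in DOX-treated against pluripotent cells, 6% for flox/- against WT and 4% for -/- against WT. At a log2 change of 3 these were 98%, 90%, 92%, 95% and 96%. Unchanged genes called in the same runs were 10, 8, 6, 2 and 6. The simulation changed all 200 genes at once, each by the same amount at every stage, with independent noise. Recovery in the real arrays can be lower, above all for differences that vary by stage. A lack of calls for genotype therefore does not show that large differences are absent.

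Alternatives fixed before the data were examined were the values as deposited, no filter on dim genes, the mean over all probe sets of a gene, leaving out each array or stage pair, leaving out the reused arrays, a variance trend with robust limma, genotype as a covariate, additive models over all arrays, no stage block, the MEF and ESC pairs alone, a common axis, WT ESC as the end point, only 2-fold genes on the axis, a 1.5-fold limit, and WT day 11 in place of WT day 8 for the single-array counts. Chosen after the data were seen were WT day 11 in place of WT day 8 in the flox/- model, the single-array list differences under other processing, and the counts of list members without the reused arrays.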

Results

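Fibroblasts can be turned into pluripotent cells by the transcription factors Oct4, Sox2, Klf4 and Myc, and the series asked how Mbd3, a subunit of the NuRD chromatin-remodelling and histone deacetylase complex, bears on this change. RNA was profiled from MEF, from MEF under DOX, and from iPSC and ESC. The cells carried both copies of Mbd3 (WT, 6 arrays), a floxed and a deleted copy (flox/-, 4 arrays) or, by their labels, no intact copy (-/-, 2 arrays). Each genotype and stage was measured on 1 array, so genotype and culture cannot be separated within a stage.

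Mbd3 lies on chromosome 10 (80392539 to 80399531, GRCm38.p6). Its log2 signal was 9.20 in WT MEF, 9.67 in WT day 4, 8.995 in WT day 8, 9.49 in WT day 11, 9.21 in WT iPSC and 9.31 in WT ESC. In flox/- cells it was 8.92 in MEF, 9.11 at day 4, 8.85 at day 8 and 8.73 in iPSC. It was 8.15 in -/- MEF and 6.74 in -/- ESC, the lowest of all 12 arrays. Over the 4 shared stages Mbd3 was 1.29-fold lower in flox/- than in WT (log2 difference -0.36 ± 0.15 SE, limma adjusted p = 0.693). In the model of arrays without DOX it was 3.47-fold lower in -/- cells (-1.79 ± 0.39 SE, adjusted p = 0.686). Neither difference passed over all genes, and where the probes lie relative to the deleted part of the gene is not known.

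Pluripotent cells differed from MEF across most of the measured transcriptome. Genes of the pluripotency network rose, some such as Dppa5a, Tdgf1 and Nanog from low signal in MEF, and fibroblast and TGF-beta response genes fell. Epithelial, cell cycle, chromatin modifier and germline genes rose with pluripotency, while macrophage, imprinted and interferon genes fell. With an estimated correlation between genes only the pluripotency list held. The 4 pluripotent arrays were compared with the 3 MEF arrays by limma. Of 13044 genes, 7827 were called, 3921 higher and 3906 lower in pluripotent cells. Without the WT ESC array of the earlier series 7762 were called.

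Dppa5a, an RNA-binding protein gene of early embryos and ESC, rose 278-fold (12.80 ± 0.14 SD, n = 4, against 4.68 ± 0.11 SD, n = 3, adjusted p = 1.68e-07). The Nodal co-receptor gene Tdgf1 rose 220-fold, the homeobox gene Nanog 129-fold, Zfp980 127-fold, Zfp640 108-fold, Lncenc1 108-fold, Sox2 105-fold, Utf1 105-fold, the nuclear receptor gene Nr0b1 97.9-fold and Apela 97.5-fold. The largest falls were in Lgr5 (40.9-fold), the growth factor gene Ptn (39.6-fold), the matrix proteoglycan gene Fmod (38.5-fold), Pcdh18 (36.9-fold), the collagen prolyl hydroxylase gene P4ha3 (35.5-fold), Lrrc17 (35.3-fold), Rspo2 (32.5-fold), Fgf7 (31.9-fold), Svep1 (30.1-fold) and Aspn (29.7-fold).

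The pluripotency list rose, with a median log2 change of 4.78 (adjusted p = 7.60e-18 and adjusted p = 0.0141 with an estimated correlation), and 34 of its 35 genes rose over all genes and 35 adjusted over the list alone. It was the only list that passed with both correlations. Of the 4 reprogramming factors, Sox2 (105-fold), Pou5f1, which encodes Oct4 (90.5-fold), and Klf4 (2.86-fold) rose and Myc fell 2.66-fold, over all genes and adjusted over the list alone. As a list they had a median of 4.01 and did not pass (adjusted p = 0.0756), but it passed with no filter on dim genes (adjusted p = 0.0342), without WT MEF (adjusted p = 0.04996) and without flox/- MEF (adjusted p = 0.0351).

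The fibroblast list fell (median -3.52, adjusted p = 1.07e-09, adjusted p = 0.448 with an estimated correlation). All 36 of its 36 genes fell over all genes and adjusted over the list alone, led by the matrix gene Postn (18.8-fold), the actin-binding gene Tagln (18.0-fold), the collagen gene Col5a2 (15.6-fold) and Thbs2 (15.5-fold). TGF-beta response genes fell too (median -2.55, adjusted p = 1.56e-05, adjusted p = 0.448 with an estimated correlation), 18 of 19 over all genes and 18 adjusted over the list alone. Among them were the ligand genes Tgfb3 (25.7-fold) and Inhba (16.1-fold) and the latency proteins Ltbp1 (14.6-fold) and Ltbp2 (12.6-fold). Epithelial genes rose (median 1.45, adjusted p = 2.62e-06, adjusted p = 0.390 with an estimated correlation), with 20 up and 1 down of 26 over all genes and 21 up and 1 down adjusted over the list alone. The cadherin gene Cdh1 rose 45.0-fold, the protease inhibitor gene Spint1 26.2-fold, Elf3 24.9-fold and Epcam 15.4-fold.

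Cell cycle genes rose (median 1.34, adjusted p = 1.07e-09, adjusted p = 0.448 with an estimated correlation), 27 of 29 over all genes and 27 adjusted over the list alone, with the replication helicase genes Mcm3 (5.17-fold), Mcm5 (5.03-fold), Mcm2 (4.59-fold) and Mcm7 (4.50-fold) in front. Chromatin modifier genes rose (median 1.10, adjusted p = 2.08e-06, adjusted p = 0.306 with an estimated correlation), with 26 up and 2 down of 34 by both adjustments. Dnmt3l, a cofactor of de novo DNA methylation, rose 16.8-fold, the 5-methylcytosine oxidase gene Tet1 16.6-fold, Hells 7.34-fold and the Polycomb cofactor gene Jarid2 6.84-fold. Germline genes that are silenced by DNA methylation in somatic cells rose (median 2.12, adjusted p = 0.00103, adjusted p = 0.550 with an estimated correlation), 15 of 20 over all genes and 15 adjusted over the list alone. They included the RNA-binding gene Dazl (27.2-fold), the piRNA pathway genes Tdrd12 (8.62-fold) and Mael (8.59-fold), and the meiotic gene Hormad1 (7.16-fold).

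Macrophage and other blood-cell genes fell (median -2.76, adjusted p = 0.00103, adjusted p = 0.676 with an estimated correlation), with 18 down of 21 over all genes and 1 up and 18 down adjusted over the list alone. The complement gene C1qb fell 15.8-fold, Fcer1g 15.4-fold, the lysozyme gene Lyz2 13.97-fold and Cd53 12.4-fold. Imprinted genes fell (median -1.23, adjusted p = 0.00730, adjusted p = 0.512 with an estimated correlation), 9 of 17 by both adjustments, with Dlk1 (26.0-fold), the growth factor gene Igf2 (7.76-fold), Sgce (7.19-fold) and the noncoding RNA gene Rian (6.54-fold). Interferon response genes fell (median -0.71, adjusted p = 0.0222, adjusted p = 0.680 with an estimated correlation), with 1 up and 9 down of 17 by both adjustments, among them Ifit2 (4.89-fold), Ifit3 (4.80-fold), the RNA sensor gene Ifih1 (4.03-fold) and Ifit1 (3.62-fold). Without the WT ESC array this list had an adjusted p of 0.0503.

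The other lists did not pass. The NuRD complex list had a median of 0.11 (adjusted p = 0.577), with 4 up and 2 down of 15 over all genes and 2 up and 2 down adjusted over the list alone. The helicase gene Chd3 fell 3.94-fold, the methyl-CpG-binding gene Mbd2 fell 1.91-fold and Gatad2a rose 1.96-fold, while Mbd3 gave -0.26 ± 0.63 SE (adjusted p = 0.739). Senescence and p53 genes had a median of -0.23 (adjusted p = 0.415), with 3 up and 6 down of 16 by both adjustments: Igfbp7 (7.29-fold), Igfbp3 (6.88-fold) and the kinase inhibitor gene Cdkn2b (6.51-fold) fell and Perp rose 3.39-fold. Trophoblast genes had a median of 0.33 (adjusted p = 0.445), with 3 up and 4 down of 16 over all genes and 3 up and 3 down adjusted over the list alone.

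Primitive endoderm genes had a median of -1.23 (adjusted p = 0.340), with 2 up and 6 down of 13 by both adjustments. The laminin gene Lama1 rose 13.5-fold, while the endocytic adaptor gene Dab2 (9.12-fold), Col4a2 (5.64-fold) and Col4a1 (4.93-fold) fell. Primed epiblast genes had a median of 0.22 (adjusted p = 0.577), with 6 up and 3 down of 12 over all genes and 6 up and 4 down adjusted over the list alone, such as Nodal (17.0-fold up), Otx2 (7.10-fold up), the Wnt antagonist gene Sfrp2 (8.75-fold down) and Fst (5.04-fold down). Muscle genes had a median of -1.38 (adjusted p = 0.0823), with 1 up and 6 down of 11 over all genes: the calponin gene Cnn1 (20.2-fold) and Myh11 (5.64-fold) fell and Mylpf rose 5.53-fold. Without the flox/- MEF array (median -1.54) or without the WT ESC array (median -1.55) the muscle list passed.

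Keratinocyte genes had a median of 0.08 (adjusted p = 0.340), and Sfn (6.14-fold), Krt17 (3.96-fold) and Perp (3.39-fold) rose among 9. Endothelial genes had a median of 0.68 (adjusted p = 0.224), with 4 up and 1 down of 9: the receptor gene Tek rose 4.15-fold, Vwf rose 2.37-fold and Flt1 fell 8.58-fold. Neural genes had 3 up and 3 down of 10 (adjusted p = 0.713), with Nefl up 6.10-fold and Map2 down 8.59-fold. Their median of 0.23 and the test pointed up and their mean of -0.03 down. The 4 genes of the 2-cell-like list, of which Zim1 is also imprinted, had a median of 0.40 (adjusted p = 0.601), and the 4 sex-linked genes -0.12 (adjusted p = 0.863). In both, limma called 0 genes.

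**Figure D1:**
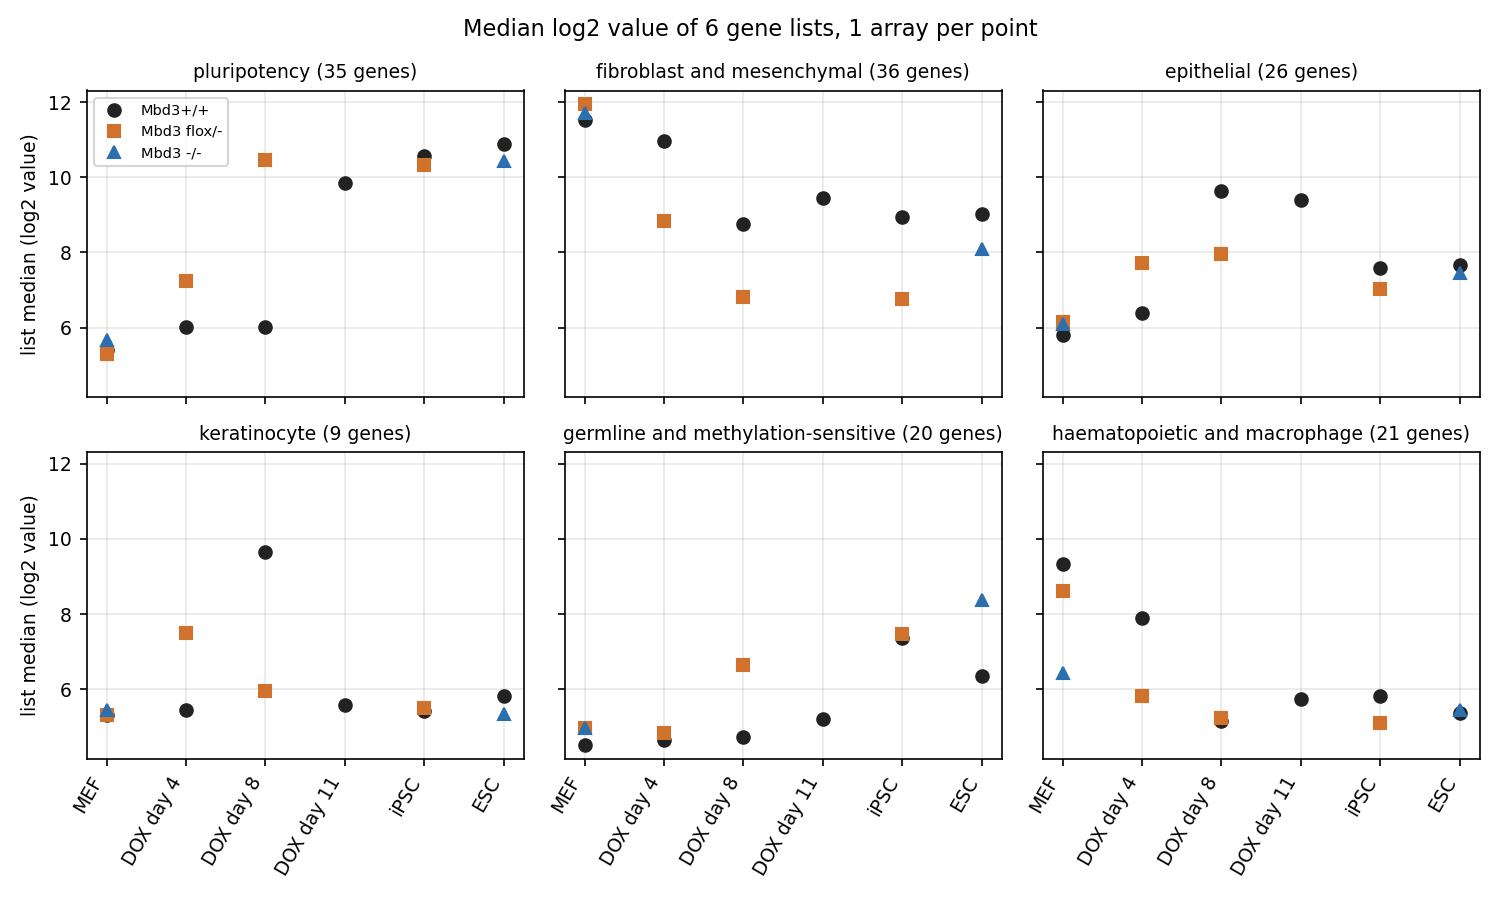
Median log2 signal of 6 gene lists in each array by stage and genotype. Each point is 1 array.

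Under DOX the cells lost fibroblast, contractile and TGF-beta genes and gained epithelial genes, Pou5f1 signal and cell cycle genes. None of these list calls held with an estimated correlation (lowest adjusted p = 0.277 with an estimated correlation). DOX switches on OSKM, so signal of Pou5f1, Klf4 and Myc under DOX may be RNA of the transgenes, which was not tested. The pluripotency genes as a list rose, yet few passed gene by gene, and the 5 DOX-treated arrays included some with and some without Nanog and Sox2 signal. The 5 DOX-treated arrays were compared with the 3 MEF arrays. Limma called 1768 genes, 767 higher and 1001 lower under DOX. Without the WT day 8 array of the earlier series it called 3165, of which 1725 were shared, and without the flox/- MEF array 150.

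Apela, a gene of an embryonic peptide hormone, rose 77.2-fold under DOX, Pou5f1 66.9-fold (11.67 ± 1.13 SD, n = 5, against 5.61 ± 0.94 SD, n = 3, adjusted p = 0.00548), 1700019D03Rik 37.6-fold, Cdh1 37.4-fold, Bex1 23.1-fold, Podxl 19.8-fold, the keratin gene Krt8 18.9-fold, Spint1 15.9-fold, Rpp25 15.2-fold and the desmosomal gene Dsp 14.6-fold. Cnn1 fell 30.5-fold, the G-protein regulator gene Rgs4 26.7-fold, Col10a1 25.6-fold, Fgf7 24.5-fold, the matrix gene Tnc 19.9-fold, Rspo2 19.8-fold, Ankrd1 19.8-fold, the myosin light chain gene Myl9 19.5-fold, Svep1 18.5-fold and Tagln 18.2-fold.

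Fibroblast genes fell (median -2.50, adjusted p = 2.52e-11, adjusted p = 0.532 with an estimated correlation), 10 of 36 over all genes and 26 adjusted over the list alone, and all 36 had negative values. TGF-beta response genes fell (median -1.88, adjusted p = 7.14e-07, adjusted p = 0.532 with an estimated correlation), 8 of 19 over all genes and 11 adjusted over the list alone, with Inhba (18.0-fold), Ltbp2 (13.6-fold) and Tgfb3 (12.3-fold). Muscle genes fell (median -1.62, adjusted p = 9.65e-05, adjusted p = 0.277 with an estimated correlation), 5 of 11 over all genes and 7 adjusted over the list alone, among them Cnn1, Myh11 (7.98-fold), the intermediate filament gene Des (7.65-fold) and Lmod1 (4.61-fold). Epithelial genes rose (median 2.41, adjusted p = 1.09e-07, adjusted p = 0.532 with an estimated correlation), 8 of 26 over all genes and 12 adjusted over the list alone.

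The pluripotency list rose (median 2.54, adjusted p = 2.95e-06, adjusted p = 0.532 with an estimated correlation), with 4 of 35 genes up over all genes and 4 adjusted over the list alone, and all 35 positive. Nanog gave 4.42 ± 1.47 SE (adjusted p = 0.0772). Its signal was 5.59 in WT day 8, 9.18 in WT day 4 and 10.36 in flox/- day 4, against 12.31 in WT day 11 and 12.55 in flox/- day 8. Sox2 was 6.01 in WT day 4, 6.03 in flox/- day 4 and 6.41 in WT day 8, against 11.91 in WT day 11 and 12.46 in flox/- day 8.

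Cell cycle genes rose (median 0.93, adjusted p = 1.98e-06, adjusted p = 0.532 with an estimated correlation), 5 of 29 over all genes and 6 adjusted over the list alone, with Mcm7 (2.90-fold), Mcm6 (2.71-fold) and Mcm5 (2.68-fold). Without the WT day 8 array 25 of 29 rose. Chromatin modifier genes rose (median 0.78, adjusted p = 7.19e-06, adjusted p = 0.532 with an estimated correlation), 6 of 34 over all genes and 14 adjusted over the list alone, with the 5-methylcytosine oxidase gene Tet2 up 3.59-fold, and 19 of 34 rose without the WT day 8 array. Macrophage genes fell (median -2.26, adjusted p = 1.41e-05, adjusted p = 0.532 with an estimated correlation), 1 of 21 by both adjustments. Imprinted genes fell (median -0.87, adjusted p = 0.0414, adjusted p = 0.532 with an estimated correlation), 4 of 17 over all genes and 5 adjusted over the list alone, with Dlk1 at -3.59 on the log2 scale and Igf2 down 3.65-fold. This imprinted call was lost without the WT day 8 array (adjusted p = 0.106), without the WT MEF array (median -0.63) and without the flox/- day 8 array (median -0.77).

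Keratinocyte genes did not pass (median 1.30, adjusted p = 0.0691), and Perp alone rose, 6.36-fold. The list passed without WT day 4 (median 1.57), without WT day 11 (median 1.57) or without flox/- day 8 (median 1.63). Neural genes did not pass either (median 0.46, adjusted p = 0.153), with the neurofilament gene Nefl up 12.9-fold and Stmn2 up 3.22-fold. Of 20 germline genes limma called 0 over all genes and 0 adjusted over the list alone (median 0.31, adjusted p = 0.333, with 4538 of all genes at unadjusted p under 0.05). Primed epiblast genes had a median of 0.20, while their mean of -0.05 and the test pointed down. The 2-cell-like list had a median of 0.08 and a mean of -0.07, with the test pointing up.

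The germline and pluripotency lists were lower in DOX-treated cells than in established pluripotent lines, and fibroblast and interferon genes were higher. None of these list calls held with an estimated correlation (lowest adjusted p = 0.693 with an estimated correlation), and the fibroblast and interferon calls were also lost when single arrays were left out. Gene by gene almost nothing passed. Limma called 1 gene, the keratin gene Krt42, which was 2.73-fold lower under DOX (5.94 ± 0.15 SD, n = 5, against 7.38 ± 0.20 SD, n = 4, adjusted p = 0.0356), while 2052 genes had an unadjusted p under 0.05. It called 1315 genes without the flox/- day 8 array, and 0 without the arrays of the earlier series, where 1407 had an unadjusted p under 0.05.

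Pluripotency genes were lower under DOX (median -2.46, adjusted p = 2.96e-11, adjusted p = 0.693 with an estimated correlation), 33 of 35 by sign. Dppa5a gave -4.75 ± 1.91 SE (adjusted p = 0.303). Germline genes were lower (median -1.82, adjusted p = 5.89e-10, adjusted p = 0.693 with an estimated correlation), 20 of 20 by sign and 6 passing adjusted over the list alone, with Dazl at -3.19 ± 1.46 SE (9.15-fold lower, adjusted p = 0.326). Cell cycle genes were lower (median -0.49, adjusted p = 2.92e-06, adjusted p = 0.693 with an estimated correlation), 28 of 29 by sign, and chromatin modifier genes too (median -0.35, adjusted p = 0.00990, adjusted p = 0.693 with an estimated correlation), 26 of 34 by sign. Fibroblast genes were higher (median 0.64, adjusted p = 0.0186, adjusted p = 0.739 with an estimated correlation), 34 of 36 by sign, and interferon genes as well (median 0.57, adjusted p = 0.0203, adjusted p = 0.693 with an estimated correlation), 14 of 17 by sign. In these 6 lists limma passed 0 genes over all genes and, germline genes aside, 0 adjusted over the list alone. The fibroblast call was lost without WT day 4 (median 0.21), WT day 11 (median 0.48), flox/- iPSC (median 0.29) or -/- ESC (median 0.61), and the interferon call without WT day 11 (median 0.47), -/- ESC (median 0.49) or WT ESC (median 0.63). Primitive endoderm genes had a median of 0.15 and a mean of 0.09 while the test pointed down.

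On the path from MEF to iPSC the flox/- arrays stood further along than WT arrays of the same day. The position of flox/- cells was 0.592 (95% interval over genes 0.578 to 0.605) at day 4 and 0.984 (0.978 to 0.991) at day 8, where 1 stands for the iPSC of the same genotype. WT cells stood at 0.347 (0.335 to 0.359) at day 4, 0.524 (0.503 to 0.546) at day 8 and 0.732 (0.721 to 0.743) at day 11. The gap was 0.244 at day 4 and 0.460 at day 8, and flox/- day 8 was 0.252 ahead of WT day 11. The day 8 gap rests on the reused WT array whose sources name both 4 and 8 days. Its Nanog signal (5.59) was below that of WT day 4 (9.18). It also correlated less with WT iPSC (0.763) than WT day 4 did (0.843). Its position of 0.524 therefore does not show a state midway to iPSC. The mean was 0.788 ± 0.277 SD (n = 2) in flox/- and 0.534 ± 0.192 SD (n = 3) in WT, a difference of 0.253 (exact permutation p = 0.4). The smallest p that this exact test of 10 splits can give is 0.1. The test ignores the day, and position rose with day in both genotypes, so the SD and the p include the day. With a common axis flox/- day 8 stood at 1.06 and WT day 11 at 0.676. Arrays of a genotype were not alike in some genes. Eif2s3y was 5.73 in WT MEF, 6.24 at day 4, 9.13 at day 8, 8.34 at day 11 and 5.02 in WT iPSC. Hprt was 8.46 in flox/- MEF, 6.51 at day 4, 5.15 at day 8 and 4.90 in flox/- iPSC. The positions may therefore include differences between the cultures besides progress towards iPSC.

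**Figure D2:**
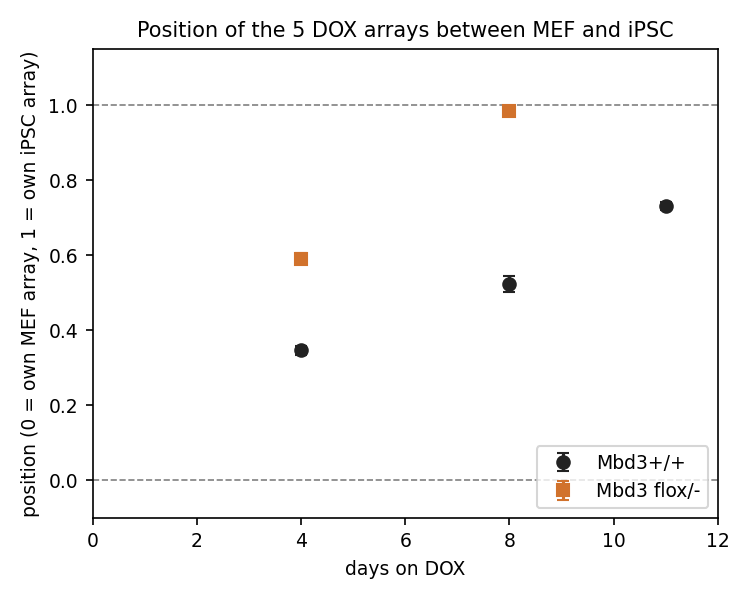
Position of the 5 DOX-treated arrays between the MEF (0) and the iPSC (1) of their own genotype. Bars are 95% intervals over genes, and each point is 1 array.

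In the model over the 4 shared stages, though not at each of them, flox/- cells had lower fibroblast, TGF-beta and macrophage genes and higher pluripotency, germline and cell cycle genes than WT cells. None of these list calls held with an estimated correlation (lowest adjusted p = 0.716 with an estimated correlation), and the pluripotency and cell cycle calls were lost without the day 8 pair. In MEF, fibroblast (0.12), TGF-beta (0.22, 15 of 19 higher), cell cycle (-0.37) and chromatin modifier genes (-0.16, 28 of 34 lower) leaned the other way. No single gene passed. Limma called 0 genes with stage as a block (smallest adjusted p = 0.693), and 852 had an unadjusted p under 0.05.

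The fibroblast list was lower in flox/- (median -1.28, adjusted p = 6.64e-14, adjusted p = 0.716 with an estimated correlation), 36 of 36 genes by sign. By stage its median difference was 0.12 in MEF, -1.91 at day 4, -1.42 at day 8 and -1.39 in iPSC. Macrophage genes were lower (median -0.90, adjusted p = 3.95e-08, adjusted p = 0.716 with an estimated correlation), 19 of 21 by sign, with -0.80 in MEF, -1.98 at day 4, -0.12 at day 8 (mean 0.12) and -0.61 in iPSC. TGF-beta response genes were lower (median -0.79, adjusted p = 5.52e-05, adjusted p = 0.716 with an estimated correlation), 17 of 19 by sign, with 0.22, -1.34, -1.89 and -0.27 at these stages. Pluripotency genes were higher (median 1.25, adjusted p = 5.90e-06, adjusted p = 0.742 with an estimated correlation), 32 of 35 by sign, with 0.04, 0.66, 3.66 and -0.00 at these stages. Germline genes were higher (median 0.74, adjusted p = 2.16e-05, adjusted p = 0.716 with an estimated correlation), 19 of 20 by sign, with 0.12, 0.07, 1.34 and 1.03. In all of these, 0 genes passed over all genes and 0 adjusted over the list alone.

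Cell cycle genes were higher in flox/- (median 0.30, adjusted p = 0.000350, adjusted p = 0.742 with an estimated correlation), 28 of 29 by sign, and chromatin modifier genes too (median 0.33, adjusted p = 0.00310, adjusted p = 0.742 with an estimated correlation), 29 of 34 by sign. Without the day 8 pair the calls were lost for pluripotency (median 0.22, adjusted p = 0.0565), cell cycle (median 0.08, adjusted p = 0.841) and chromatin modifier genes (median 0.04, adjusted p = 0.538). With WT day 11 in place of WT day 8, a choice made after the data were seen, cell cycle (median 0.09) and chromatin modifier genes (median 0.11) did not pass. Calls were also gained: interferon genes passed in that setting (median -0.47) and without the MEF pair (median -0.42). Epithelial genes passed without the day 4 pair (median -0.63). Keratinocyte genes passed without the day 4 pair (median -1.52) and, with the opposite sign, without the day 8 pair (median 0.42).

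The sex-linked genes as a list of 4 were higher in flox/- (median 1.05, adjusted p = 0.0291, adjusted p = 0.716 with an estimated correlation). The Y-linked translation factor gene Eif2s3y was 11.99-fold higher (3.58 ± 0.56 SE) and passed adjusted over the list alone, with values of 5.73 in WT MEF, 6.24 in WT day 4, 9.13 in WT day 8 and 5.02 in WT iPSC against 10.06, 9.92, 10.70 and 9.78 in flox/-. It was 8.34 in WT day 11 and 9.20 in WT ESC, so the WT arrays were not alike. In the MEF, day 4 and iPSC pairs a difference in cell sex therefore cannot be told apart from the Mbd3 genotype. The Y-linked gene Uty did not follow in MEF (9.614 in WT, 9.654 in flox/-) but did in iPSC (7.034 and 9.507). Xist, the noncoding RNA of X inactivation, ran against the list (-1.14 ± 0.90 SE): it was 7.51 in WT MEF, 10.81 in WT day 4, 11.62 in WT day 8 and 9.79 in WT iPSC, and 9.69, 9.41, 8.91 and 7.15 in flox/-. Without the MEF pair the sex-linked list did not pass (median 1.07). Among imprinted genes the growth-factor receptor adaptor gene Grb10 was 5.29-fold lower (-2.40 ± 0.19 SE) and passed adjusted over the list alone. Medians and means differed in sign, or the test from them, for NuRD (median 0.04, mean -0.07), senescence (median 0.20, mean -0.07), 2-cell-like (median 0.17, mean -0.02), imprinted (median 0.08, mean -0.07), endothelial (median 0.10, mean -0.15) and neural genes (median 0.24, mean -0.10). None of these 6 passed.

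In MEF, flox/- cells had more interferon and senescence signal and less macrophage and cell cycle signal than WT cells. At least 2-fold apart were 304 genes higher and 234 lower in flox/- (r across genes 0.970). The largest differences were Serpina3n, a protease inhibitor gene induced in inflammation (35.9-fold higher), Eif2s3y (20.1-fold), the alcohol dehydrogenase gene Adh1 (13.96-fold), Anxa8 (11.1-fold) and Cyp4a12b (10.2-fold), and on the lower side the imprinted gene Zim1 (33.4-fold), Sfrp4 (15.6-fold), the transglutaminase gene F13a1 (9.86-fold), Nrk (7.69-fold) and the hypoxia-induced gene Car9 (7.36-fold). Interferon genes were higher (median difference 0.81, percentile 100 among random lists, 16 of 17 genes), with Ifit1 4.69-fold, Usp18 3.74-fold and Ifit3 3.16-fold higher. Senescence genes were higher (0.59, percentile 100, 14 of 16), with Igfbp3 at 3.97-fold and Cdkn2b at 2.54-fold. Macrophage genes were lower (-0.80, percentile 0, 21 of 21) and cell cycle genes as well (-0.37, percentile 0, 26 of 29). Among imprinted genes (-0.28, percentile 0.01) Cdkn1c was 5.66-fold, Grb10 4.94-fold and Mest 2.93-fold lower.

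At day 4, flox/- cells had lost more fibroblast and macrophage signal and had more epithelial, keratinocyte and pluripotency signal than WT cells, while Myc, Klf4 and Pou5f1 were lower. Genes 2-fold apart were 629 higher and 1049 lower in flox/- (r = 0.913). Cyp4f39 was 56.5-fold higher, the water channel gene Aqp3 22.2-fold, the keratinocyte gene Krtdap 22.0-fold, Krt8 21.4-fold and C330024D21Rik 20.7-fold. E330013P04Rik was 28.3-fold lower, Fndc1 21.1-fold, AI506816 17.8-fold and the imprinted gene Mest 15.7-fold, and the purine salvage gene Hprt differed by -4.26 on the log2 scale. Epithelial genes were higher (median difference 1.13, percentile 100, 26 of 26), with Dsp 9.62-fold and the splicing factor gene Esrp1 8.60-fold higher. Keratinocyte genes were higher (1.61, percentile 100, 9 of 9), with Krt14 at 5.23-fold and Lgals7 at 4.55-fold. Pluripotency genes were higher (0.66, percentile 100, 30 of 35), with Utf1 17.8-fold and Nr0b1 7.67-fold higher.

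The reprogramming factors at day 4 had a median difference of -2.60 (percentile 0): Myc was 15.7-fold, Klf4 8.01-fold and Pou5f1 4.58-fold lower in flox/-, and Sox2 was 1.02-fold higher. In flox/- day 4 Klf4 (7.198) and Myc (6.883) lay below flox/- MEF (9.494 and 9.564), while Pou5f1 was 9.715 against 4.645. Whether these signals came from the transgenes or from the cells' own genes was not tested. Fibroblast genes were lower (-1.91, percentile 0, 36 of 36), with the smooth muscle actin gene Acta2 5.55-fold and the mesenchymal transcription factor gene Snai2 5.53-fold lower. TGF-beta response genes were lower by the same measure (-1.34), interferon genes too (-0.76), and so were macrophage genes (-1.98, percentile 0, 21 of 21), with C1qb 14.8-fold and C1qc 10.2-fold lower. The macrophage list median was 7.89 in WT day 4 and 5.81 in flox/- day 4. Cell cycle genes were higher (0.48, percentile 100).

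At day 8, flox/- cells carried the pluripotency network at the level of iPSC, while the WT array lacked Nanog and Sox2 and carried keratinocyte genes. This was the widest gap of all pairs (1708 genes higher and 2439 lower in flox/-, r = 0.743). Dppa5a was 268-fold higher, Tdgf1 218-fold, Zfp980 217-fold, Zfp640 171-fold and Nr0b1 131-fold. Their WT day 8 signals of 4.93, 4.49, 3.51, 3.89 and 5.07 lay near or below the lower quartile of that array (4.66), so the background limits these folds and their order. On the lower side were the epithelial gene Mall (164-fold), the keratin gene Krt16 (161-fold), the epidermal lipoxygenase gene Alox12b (133-fold), Nccrp1 (112-fold) and the aldehyde dehydrogenase gene Aldh3a1 (105-fold). Pluripotency genes were higher (median difference 3.66, percentile 100, 33 of 35), with Nanog 124-fold and Sox2 66.5-fold higher, while Myc was 13.7-fold lower. Cell cycle (1.28, percentile 100, 27 of 29), germline (1.34, percentile 100, 20 of 20) and chromatin modifier genes (0.95, percentile 100) were higher, with Dazl 56.3-fold, Tet1 48.8-fold, Hormad1 14.04-fold and Dnmt3l 11.8-fold higher.

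Keratinocyte genes at day 8 were lower in flox/- (-3.50, percentile 0, 9 of 9), with Krt14 67.0-fold, the desmoglein gene Dsg3 40.4-fold, Krt6a 27.6-fold and Krt17 26.4-fold lower. The filter on dim genes let in members that were high in WT day 8, such as Krt1 (8.23 there, 4.74 in MEF). It left out Krt5 (5.37 in WT day 8), Krt15 (5.52) and Krt10 (6.05). The counts and percentiles of this list at days 4 and 8 thus partly reflect the filter. Epithelial genes were lower (-1.28, percentile 0.01, 24 of 26), such as Krt19 (13.6-fold) and Dsp (11.8-fold). Fibroblast genes were lower (-1.42, percentile 0, 30 of 36), such as the matrix proteoglycan gene Dcn (89.0-fold) and the mesenchymal homeobox gene Prrx1 (53.9-fold), and TGF-beta response genes too (-1.89). The keratinocyte list median was 9.64 in the WT day 8 array and 5.94 in flox/- day 8, against 5.57 in WT day 11.

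Set against WT day 11, flox/- day 8 cells differed less than against WT day 8, with lower fibroblast, interferon, TGF-beta, imprinted and epithelial genes. There were 532 genes higher and 1348 lower (r = 0.901). Accsl was 23.8-fold higher, C330024D21Rik 22.8-fold, Olfr153 18.2-fold, Nexmif 15.8-fold and Hunk 14.8-fold. The matrix genes Prelp (51.4-fold), Dcn (48.9-fold) and Lum (39.8-fold), Hprt (50.7-fold) and Lyz2 (36.6-fold) were lower. Fibroblast genes had a median difference of -2.36 (percentile 0, 35 of 36 lower), interferon genes -1.45 (percentile 0, 16 of 17 lower, with Oasl2 6.20-fold), TGF-beta response genes -1.42 (percentile 0, 16 of 19 lower), epithelial genes -0.96 (percentile 0, 22 of 26 lower) and imprinted genes -1.09 (percentile 0, with Grb10 13.1-fold lower). Pluripotency genes were higher (0.51, percentile 100, 27 of 35), with Zfp42 10.6-fold higher and Dppa3 10.2-fold lower. Germline genes were higher (0.88, percentile 100, 19 of 20), with Dazl 13.3-fold higher. Keratinocyte genes differed by -0.02.

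In iPSC the pluripotency genes were level between the genotypes, while fibroblast genes were lower and germline genes higher in flox/-. Genes 2-fold apart were 245 higher and 417 lower (r = 0.960). Eif2s3y was 27.0-fold higher, the Polycomb-related gene Scml2 16.6-fold, Nlrp4c 14.3-fold, 1700018B24Rik 13.7-fold and Olfr836 10.8-fold. Hprt was 66.4-fold lower, Dcn 65.0-fold, Lyz2 50.4-fold, Postn 40.9-fold and the matrix gene Bgn 33.5-fold. Fibroblast genes had a median difference of -1.39 (percentile 0, 33 of 36 lower), with the collagen cross-linking gene Lox 31.5-fold and Thbs2 23.5-fold lower. Germline genes were higher (1.03, percentile 100, 17 of 20), with the piRNA pathway gene Asz1 10.1-fold, the tubulin gene Tuba3b 6.12-fold and Slc25a31 4.14-fold higher, and Tdrd12 7.86-fold lower. Macrophage (-0.61, percentile 0), interferon (-0.49, percentile 0, 16 of 17 lower) and epithelial genes (-0.45, percentile 0, 20 of 26 lower) were lower. Pluripotency genes had percentile 46.6, with Zfp42 2.71-fold higher and Lin28a 2.76-fold lower. Imprinted genes leaned up (0.31, percentile 99.99), with Peg10 4.85-fold higher and Grb10 4.81-fold lower.

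In the model of the -/- arrays macrophage and fibroblast genes were lower and germline genes higher than in WT, none of which held with an estimated correlation (lowest adjusted p = 0.777 with an estimated correlation). The macrophage shift rests on the -/- MEF array, where the Mbd3 signal was 8.15, and the germline and fibroblast shifts on ESC. Between the MEF arrays alone fibroblast genes had a median difference of 0.11, with 24 of 36 higher in -/-. Over the 7 arrays without DOX, limma called 0 genes for -/- (smallest adjusted p = 0.686), and 907 had an unadjusted p under 0.05. Germline genes were higher (median 1.39, adjusted p = 1.09e-06, adjusted p = 0.777 with an estimated correlation), 17 of 20 by sign, with 0 passing over all genes and 2 adjusted over the list alone. Asz1 was 10.6-fold higher (3.41 ± 1.51 SE), Dazl 8.01-fold (3.002 ± 1.27 SE), Tuba3b 2.72 and Slc25a31 2.05 ± 0.35 SE. Macrophage genes were lower (median -1.42, adjusted p = 5.75e-07, adjusted p = 0.777 with an estimated correlation), 21 of 21 by sign, and fibroblast genes as well (median -0.58, adjusted p = 0.000772, adjusted p = 0.842 with an estimated correlation), 30 of 36 by sign. Without the WT ESC or the -/- ESC array, where the fit still draws on the flox/- and iPSC arrays, fibroblast (median -0.32, adjusted p = 0.264) and germline genes (median 0.47, adjusted p = 0.115) did not pass, and without -/- MEF the macrophage median turned to 0.03.

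Primed epiblast genes did not pass for -/-, although the Wnt antagonist gene Sfrp2 was higher adjusted over the list alone (1.60 ± 0.25 SE). Median, mean and test did not share a sign for pluripotency (median -0.01, mean 0.02), reprogramming factor (median -0.11, mean -0.19), senescence (median 0.13, mean -0.03), trophoblast (median -0.01, mean 0.16), 2-cell-like (median 0.14, mean -0.40) and keratinocyte genes (median -0.02, mean 0.02), and none of these passed. Eif2s3y was 10.04 in -/- MEF and 10.38 in -/- ESC, against 5.73 in WT MEF, 5.02 in WT iPSC and 9.20 in WT ESC. Xist was 5.22 in -/- MEF and 7.51 in WT MEF, while Uty hardly differed there (9.44 and 9.61). In the MEF pair a difference in cell sex therefore cannot be told apart from the Mbd3 genotype, which also bears on the model.

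The -/- MEF array had lower macrophage signal than WT MEF and very low signal of several imprinted genes. Its Mbd3 signal of 8.15, against 9.20 in WT MEF and 6.74 in -/- ESC, does not by itself show that Mbd3 RNA was absent. There were 399 genes higher and 516 lower than in WT MEF (r = 0.945). Serpina3n was 48.7-fold higher, Olr1 34.9-fold, the matrix protease gene Mmp3 27.8-fold, Cyp4a12b 27.7-fold and Cck 27.1-fold. Grb10 was 102-fold lower, Mest 79.0-fold, F13a1 51.0-fold, the macrophage mannose receptor gene Mrc1 44.5-fold and AI506816 40.5-fold. Macrophage genes had a median difference of -2.98 (percentile 0, 21 of 21 lower), with C1qc 19.02-fold and C1qb 14.4-fold lower. Imprinted genes had -0.39 (percentile 0.01), with Zim1 37.4-fold and the growth restrictor gene Cdkn1c 7.29-fold lower. Mbd3 was 2.08-fold lower. Pluripotency (0.11, percentile 79.8) and fibroblast genes (0.11, percentile 88.0) lay inside the random range. Hprt was 5.33 in -/- MEF and 10.32 in WT MEF.

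The -/- ESC array carried germline genes above WT ESC, with lower TGF-beta, contractile and fibroblast genes. There were 506 genes higher and 790 lower (r = 0.930). Usp26 was 103-fold higher, Asz1 78.2-fold, 1700018B24Rik 62.8-fold, Dazl 50.2-fold and Nxf3 50.01-fold. The WT ESC signals of Usp26 (4.40), Asz1 (3.95), 1700018B24Rik (4.58), Nxf3 (4.42) and Tuba3b (4.385) lay below the lower quartile of that array (4.69), so the background limits their folds. Hprt was 35.1-fold lower, Cnn1 27.2-fold, Accsl 18.97-fold, the smooth muscle actin gene Actg2 16.7-fold and 2210409E12Rik 16.1-fold. Germline genes had a median difference of 2.44 (percentile 100, 17 of 20 higher), with Tuba3b 28.5-fold and the piRNA helicase gene Mov10l1 10.2-fold higher. TGF-beta response genes were lower (-1.51, percentile 0, 16 of 19), with Tgfb3 12.8-fold, Inhba 10.02-fold and Tgfb2 9.52-fold lower. Fibroblast genes were lower (-1.16, percentile 0, 31 of 36), with Tagln 12.6-fold and Acta2 7.27-fold lower while Dcn was 8.03-fold higher, and muscle genes were lower (-0.74, percentile 0.03, 11 of 11).

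Pluripotency genes in -/- ESC had a median difference of -0.20 (percentile 11.2, 23 of 35 lower), with the Nodal antagonist gene Lefty2 6.86-fold higher and Nr0b1 4.83-fold and Lin28a 3.02-fold lower. Primitive endoderm genes were higher (0.37, percentile 99.6, 12 of 13), with Srgn 17.7-fold, Cubn 9.06-fold and the transcription factor gene Gata6 3.17-fold higher. The DNA methyltransferase gene Dnmt3a was 3.21-fold higher and Dnmt3b 3.36-fold lower, and the maternally expressed RNA genes Rian (8.17-fold) and Meg3 (4.97-fold) were lower. Among primed epiblast genes Otx2 was 3.62-fold higher and Foxd3 5.06-fold lower. Mbd3 was 5.98-fold lower. Macrophage genes differed by 0.03 (percentile 89.5).

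**Figure D3:**
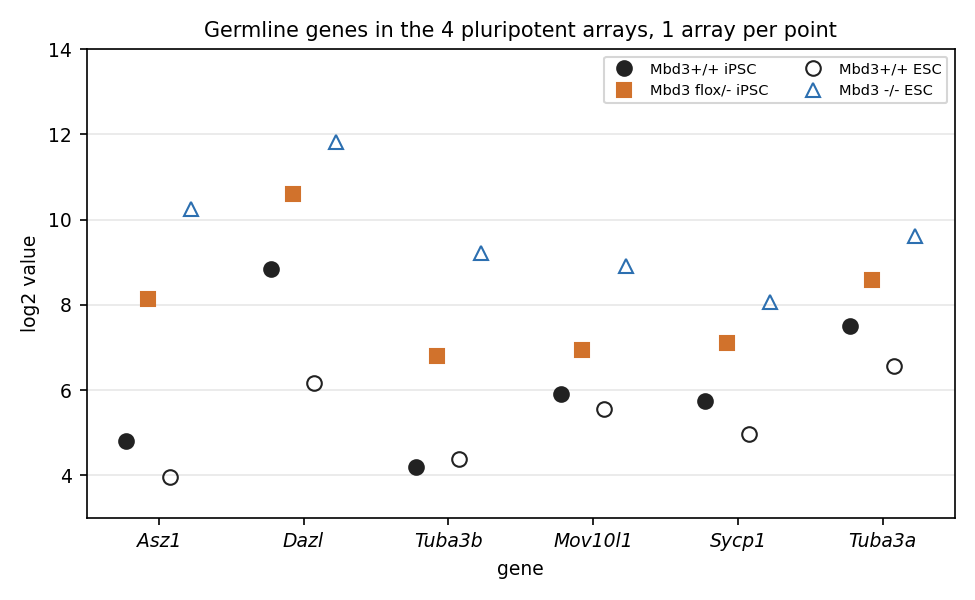
Log2 signal of Asz1, Dazl, Tuba3b, Mov10l1, Sycp1 and Tuba3a in the 4 pluripotent arrays. Each point is 1 array.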

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

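All tests of the keratinocyte genes below were chosen only after the result was seen, and 2 were revised after their values were known: the rule of the keratin test, which moved from counting against whole keratinocytes to open, and the test of the sampling day, which was replaced. Which group medians stand apart was judged by a fixed rule on the gene list medians of arrays of the same cell state. The rule was applied 47 times and picked 8 values, and by chance alone it would be expected to pick some. Differences between stages were picked by their opposite sign and rest on 1 array each, without a test.

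The keratinocyte list stood at 9.64 in the WT day 8 array, against 5.45 in WT day 4, 5.57 in WT day 11 and 7.51 in flox/- day 4, so that flox/- minus WT was 1.61 at day 4 and -3.50 at day 8. An offset shared by the arrays of the earlier series could raise these genes, but WT ESC of that series exceeded the other pluripotent arrays by only 0.393 against an excess of 4.13 at day 8, which argues against it. Whole keratinocytes mixed into the culture might bring them in, and the median excess of Krt5, Krt15, Krt1 and Krt10 of 0.388 beside 6.87 for Krt14 leaves this open: Krt1 was raised by 3.49, while Krt5 (0.384), Krt15 (0.181) and Krt10 (0.392) hardly moved and stayed low on every array. A sample taken at day 4 or day 11 might differ in this way. The list exceeded the higher of these WT arrays by 4.07 while they differed from each other by 0.118. This restates the flagged gap against arrays outside the earlier series, and flox/- day 4 stood at 7.51, so it cannot decide on the day. Whole keratinocytes and the sampling day stay open, and no biological explanation was tested.

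The reprogramming factors in flox/- day 4 had the lowest median of the DOX-treated arrays, 7.04, with the nearest at 10.53. The MEF arrays stood at 7.31 (WT), 7.55 (flox/-) and 7.51 (-/-), so as a list the factors gave no sign of induction in flox/- day 4. Pou5f1 was higher there than in flox/- MEF (9.715 against 4.645). How far the factors were induced was not tested, which limits all day 4 comparisons of flox/- with WT, the position gap included. The NuRD list was lowest in WT day 8, at 10.45 against 10.77 in the nearest array. The germline list was highest among DOX-treated arrays in flox/- day 8, at 6.64 against 5.21. The 2-cell-like list was highest among DOX-treated arrays in WT day 11, at 7.14 against 5.88, and among pluripotent arrays in flox/- iPSC, at 6.87 against 5.55. Its median was 7.30 in WT MEF, and its 4 kept genes include the imprinted gene Zim1 (10.69 in WT MEF). The list median does not by itself show a 2-cell-like state. The interferon list was highest among pluripotent arrays in WT iPSC, at 6.81 against 6.09. The macrophage list was highest among DOX-treated arrays in WT day 4, at 7.89 against 5.81. The muscle list was highest among DOX-treated arrays in WT day 11, at 6.71 against 6.27. The epithelial list was 1.13 higher in flox/- than in WT at day 4, and at day 8 the difference was -1.28.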

How the results depend on the processing

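The results were recomputed under the alternatives named with the processing, and the cause of each change was not tested. For pluripotent cells against MEF the count of called genes ran from 6449 to 7762 with each array left out, and of 1560 values of named genes 1503 kept their call, 43 were weaker and 14 stronger. For DOX-treated cells against MEF it ran from 150 without flox/- MEF to 3165 without WT day 8, with 402 without -/- MEF, 414 without WT MEF, 659 without WT day 11 and 688 without flox/- day 4, against 1768. It was 3165 without the arrays of the earlier series and 508 with genotype as a covariate, and of 1652 named-gene values 1396 kept their call, 217 were weaker and 39 stronger.

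For DOX-treated against pluripotent cells, where 1 gene was called, the count ran from 0 to 1315 with each array left out. It was 0 without the arrays of the earlier series, with a variance trend and robust limma, and with genotype as a covariate, and 1315 without flox/- day 8. Of 1575 named-gene values 1537 kept their call, 11 were weaker and 27 stronger. In the flox/- and -/- models 0 genes were called in every setting. That 1260 of 1260 and 1442 of 1442 values kept their call was thereby fixed and does not show stability.

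The number of lists passing ran from 10 to 12, 8 to 11, 4 to 9 and 7 to 10 in the first 4 comparisons with each array or pair left out. For -/- against WT, with 3 lists passing, it ran from 1 to 8: 8 without WT MEF, 5 without WT iPSC, flox/- MEF, flox/- iPSC or -/- MEF, and 1 without -/- ESC, without WT ESC or without the arrays of the earlier series. List calls stayed the same for 234 of 242, 253 of 264, 267 of 286, 180 of 198 and 220 of 242 values. The only reversal was the macrophage list of -/- against WT without -/- MEF, with a median of 0.0331, while without -/- ESC, without WT ESC or without the arrays of the earlier series it was -2.85. With WT day 11 in place of WT day 8, chosen after seeing the data, the flox/- model gave 0 genes and 7 lists.

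With a 1.5-fold in place of a 2-fold limit the genes apart were 1612 in MEF, 3836 at day 4, 6581 at day 8, 3767 for flox/- day 8 against WT day 11 and 1695 in iPSC, and for -/- cells 2271 in MEF and 3337 in ESC. With WT day 11 in place of WT day 8 the 4147 genes of day 8 became 1880. In each single pair 30 of 30 named-gene values stayed the same, and the lists outside the random range changed little under other processing, an alternative chosen after seeing the data.

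On a common axis the positions were 0.311 for WT day 4, 0.486 for WT day 8, 0.676 for WT day 11, 0.640 for flox/- day 4 and 1.06 for flox/- day 8. With WT ESC as the end point they were 0.590 for WT day 8, 0.717 for WT day 11, 0.671 for flox/- day 4 and 1.09 for flox/- day 8. The order of the 5 arrays stayed the same on a common axis and with WT ESC as the end point.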

Other observations

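All tests of the fibroblast and germline genes below were chosen only after the result was seen, and the splits of arrays were chosen before. After their values were known, both fibroblast tests were replaced and their rules rewritten, and the germline dilution rule gained a clause on quartiles. Several patterns were not asked for by the design. The differences of flox/- iPSC from WT iPSC and of -/- ESC from WT ESC shared genes across the transcriptome (Pearson r = 0.326, Spearman 0.188). There 105 genes were 2-fold higher in both against 9.50 by chance and 162 lower in both against 25.3. The -/- MEF and -/- ESC differences were not correlated (r = -0.0276, Spearman -0.0327), with 23 higher in both against 15.5 by chance and 54 lower in both against 31.3. For flox/- MEF and flox/- iPSC r was 0.0859 (Spearman 0.165), with 21 higher in both against 5.71 by chance and 29 lower in both against 7.48. These chance counts take every gene as equally likely to differ. Even the uncorrelated -/- pairs exceeded them, so an excess alone does not show a shared response. Line of origin and Mbd3 genotype cannot be told apart in these overlaps. The WT day 8 array correlated with WT day 4 and WT day 11 alike (0.8225 and 0.8228), and most with flox/- day 4 (0.865).

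Fibroblast genes were higher in WT iPSC than in flox/- iPSC (median difference -1.39, flox/- minus WT), while pluripotency genes were level. RNA of fibroblasts in the WT iPSC sample could produce this: all 17 genes at least 16-fold higher in MEF than in ESC were higher in WT iPSC (49.7% of all genes were), as were the macrophage genes Lyz2 (10.32 against 4.67) and C1qb (8.05 against 5.09). Yet these 17 genes implied shares of MEF RNA whose quartiles, 1.34% and 5.43%, were 4.04-fold apart (median 2.99%), so a single share of the measured MEF was not shown and other fibroblasts, such as feeders, were not measured. An effect of the Mbd3 genotype on fibroblast genes in pluripotent cells may also lower them, and the same genes had a median difference of -1.16 between -/- ESC and WT ESC. Both explanations stay open. The fibroblast list median in WT iPSC (8.94) was close to that in WT ESC (9.03). It was 8.09 in -/- ESC and lowest in flox/- iPSC (6.77), so as a list WT iPSC did not stand apart from WT ESC. Of the 36 genes, 33 were lower in the iPSC pair and 31 in the ESC pair. That 28 were lower in both is about what unrelated pairs would give. The other 8 went opposite ways, and the sizes of the differences did not run together (r = -0.331). Dcn, for example, differed by -6.02 in iPSC and 3.01 in ESC, and Lum by -4.51 and 1.82.

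Germline genes were higher in both Mbd3-mutant pluripotent arrays, at list medians of 7.46 in flox/- iPSC and 8.36 in -/- ESC against 7.35 in WT iPSC and 6.36 in WT ESC. An offset of the earlier series could lower WT ESC alone. Outside that series flox/- iPSC exceeded WT iPSC by a median of 1.03 over the genes (quartiles 0.565 to 1.79), with 17 of 20 higher. This argues against an offset as the cause of the iPSC difference, although the list medians of these arrays lie close. The iPSC pair cannot show whether WT ESC was lowered, so an offset stays open for the ESC pair. Dilution by fibroblast RNA might lower the germline genes in WT iPSC, but the pluripotency genes differed by -0.0021 (quartiles -0.273 to 0.170), which argues against it. The line of origin rather than Mbd3 may carry the difference, since Hprt separated the same arrays, with a gap of 1.87 over all WT and mutant arrays and 5.30 between their medians. Loss of Mbd3 and line of origin cannot be told apart here. In the iPSC pair cell sex cannot be told apart from them either, as Eif2s3y was 5.02 in WT and 9.78 in flox/- iPSC.

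The arrays were regrouped with the group sizes kept, with the real grouping counted among the splits. For pluripotent cells against MEF the real grouping gave the most genes called: of all 35 splits only the real one reached 7827, and the highest other count was 58. The real grouping came first for DOX-treated cells against MEF as well, where of all 56 splits only the real one reached 1768. The highest other count there was 1137, from the split that set WT day 11, flox/- day 4 and flox/- day 8 apart from the MEF, WT day 4 and WT day 8 arrays. With flox/- MEF left out, the real grouping itself gave 150. By the rule set beforehand both results count against chance. Arrays that share a genotype or a time course are not freely exchangeable, so chance is not excluded. For DOX-treated against pluripotent cells chance could not be excluded, since 7 of 100 drawn splits reached the real count of 1. The highest other was 116, from the split that exchanged flox/- day 8 and WT ESC, which points to a structure of the samples besides the treatment. For flox/- against WT the 8 splits are too few, with 0 in the real grouping and 0 as the highest other.

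For the number of lists passing, chance could not be excluded in pluripotent cells against MEF (10 real, highest other 12, 11 of 35 splits as high), in DOX-treated cells against MEF (9 real, highest other 16, 20 of 56 splits) or in DOX-treated against pluripotent cells (6 real, highest other 13, 90 of 100 splits). The 8 splits for flox/- against WT are too few, with 8 lists real, 9 as the highest other and 2 splits as high.

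Hprt was 8.46 in flox/- MEF, 6.51 in flox/- day 4, 5.15 in flox/- day 8 and 4.90 in flox/- iPSC, against 10.32, 10.76, 11.17 and 10.96 in the WT arrays of these stages. The imprinted genes Grb10, Mest and Zim1 were lower than in WT MEF in both mutant MEF arrays, by 4.94-, 2.93- and 33.4-fold in flox/- and by 102-, 79.0- and 37.4-fold in -/-. The macrophage list median was 9.33 in WT MEF, 8.60 in flox/- MEF and 6.44 in -/- MEF.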
